A study of Homo sapiens with 4 samples.

How the data were processed

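Total RNA of NB4-R4 cells was measured on 4 Affymetrix expression arrays, 2 from cells given the vehicle DMSO and 2 from cells given MK-8776 at 4 µM, all at 96 h. The labels call the arrays of a group biological replicates and say no more of how the cultures were separated, so p-values measure the spread between these samples. The labels also say that RNA was taken from live cells with TRIzol, biotin-labelled, and amplified before hybridisation.

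The deposited values are log2 expression values, 1 per array feature and array. Per the submitters' processing notes they were made with RMA, which corrects the background, normalizes between arrays and summarises the probes of a feature, with genome build hg38. The version and settings of RMA, the scanner and any filter are not given in the sources used here. That the scale is log2 was taken from the values, which run from 2.16 to 18.54 with array medians between 5.76 and 5.79. A variant of RMA is not ruled out by the sources used here, and one with another scale would change the size of the log2 changes and folds. The values carry 2 decimals. Scanner files were not used here, so there is no detection call and no measure of background per feature. The number of arrays, not a depth of counting, limits the precision. RMA makes the arrays alike in distribution, so all changes are relative to the other genes, and a change of the whole RNA content would not be seen.

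The table holds 21448 features. The platform annotation gave exactly 1 gene symbol for 17709 of them, several for 0, and none for 3739, which are unnamed here. The annotation was matched by gene number to a RefSeq gene table (assembly GRCh38.p14), and all 17709 symbols were found there. For 20 genes with over 1 feature the feature with the highest mean over the 4 arrays was taken. In 7 of these the features differed in the sign of the change, and 2 of the 20 genes had a feature past the threshold. This left 17687 genes. Coordinates are those of the gene table, counted from 1.

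The values were tested as deposited with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no filter on dim features), MK-8776 against DMSO, with Benjamini-Hochberg adjustment over the 17687 genes and a threshold of 0.05. The fit had 2 residual degrees of freedom per gene and borrowed 6.30 more from the other genes, with a prior SD of 0.230. An exact permutation test of 2 arrays against 2 cannot go below p = 0.333 (two-sided), so single genes were judged by the limma fit alone. In 20 simulated data sets made from the means and spread of these 17687 genes, with 200 genes changed, the fit recovered 13.5% of genes changed by 1 on the log2 scale, 96.2% of those changed by 2 and 99.5% of those changed by 3, and 5.95% of its calls were false. A gene that did not pass may thus have changed 2-fold. The simulated genes varied independently, with spreads drawn from the fit's own prior and no trend with level. Their false share was thus near the threshold by design and does not measure that of the real data. With more changed genes than the 200 simulated the adjusted threshold is looser, so the simulated recovery need not hold for the real data.

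Fixed before the data were examined were the design, the alternatives, 27 gene lists and the rule for the genes named. Each list with at least 5 measured members was tested with camera (limma) at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 27 lists. Camera with an estimated correlation, and fry, which tests whether a list's genes move on balance one way, were run beside that test. With an estimated correlation camera also takes its p from the 2 residual degrees of freedom, so it has little power here. In 20 simulated data sets with 1 list lowered by 0.5, camera with the preset correlation found the list 20 times and called 1 of 520 other list tests. These simulations held no correlation between genes. 11 symbols stand in over 1 list. List members without a single gene name on the array were not analysed here.

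Named in the text are CHEK1, the 12 largest rises and the 12 largest falls among genes past the threshold whose higher group mean lay above the median of all values (5.77), and up to 4 members of each list past the threshold with the largest change. Where no member passed, the 2 with the largest change are given as values. Genes outside this rule appear in the closing section, and in the results as a few list members given for their level or direction. They were chosen after their values were seen.

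The alternatives were quantile normalization, median centring, only features above the median level, a variance trend with and without robust estimation, a replicate block, all 21448 features, a test against a fold of 1.2, a fold of 1.5 in place of 2, and leaving out each array in turn. The replicate numbers 1 and 2 occur in both groups, and the labels tie them to no shared day, batch or culture. No scan date or batch is given in the sources used here.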

Results

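NB4-R4 is a subclone of the acute promyelocytic leukaemia line NB4 that no longer responds to all-trans retinoic acid, the drug that normally drives such cells to mature. MK-8776 is an inhibitor of CHK1, the kinase that slows the cell cycle when DNA replication stalls. Expression in cells given MK-8776 at 4 µM for 96 h was compared with that in cells given DMSO for the same time, with 2 arrays per group. The comparison asks which transcripts differ after MK-8776 at this dose and time in these resistant cells. CHK1 activity was not measured in these data. Values below are RMA expression on the log2 scale, given as mean ± SD over the 2 arrays of a group (n = 2), and changes are log2 fold changes, MK-8776 minus DMSO, with their standard error (SE) and adjusted p from limma. The correlation across genes was 0.993 between the DMSO arrays and 0.993 between the MK-8776 arrays, against 0.981 to 0.989 between arrays of different groups. The median SD within a group was 0.163 in DMSO and 0.170 in MK-8776.

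After MK-8776, genes of the lysosome, inflammation, heat shock and neutrophil maturation lists were among those that rose, such as SQSTM1, CCL2, HSPH1 and S100A8. Genes of the mitosis, hypoxia and glycolysis, and primary granule lists were among those that fell, such as KIF20A, ALDOC and CTSG. Of the 17687 genes tested, 652 passed the threshold, of which 294 rose and 358 fell. Among them 610 changed 2-fold or more, 276 upward and 334 downward. The smallest absolute log2 change among the 652 was 0.925, so the share of 2-fold changes largely follows from passing the test. Both MK-8776 arrays lay on one side of both DMSO arrays in 48.2% of all genes, against 33.3% by chance with 2 arrays against 2. The same held for all 652 genes that passed, so a lack of overlap in a called gene adds no further support. The number of calls rests on all 4 arrays. The limma fit called 0 genes without DMSO replicate 1, 0 without DMSO replicate 2, 7 without MK-8776 replicate 1 and 34 without MK-8776 replicate 2, with 2620, 1815, 2024 and 3017 genes at an unadjusted p under 0.05.

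The largest rise was in HMOX1, which encodes haem oxygenase 1 (feature TC2200007204.hg.1, chromosome 22, 35381096 to 35394207, GRCh38). It went from 3.96 ± 0.06 to 10.80 ± 1.06, a change of 6.84 (SE 0.42, adjusted p = 0.000483, limma). Its DMSO level lay under the lower quartile of all values (3.97), so the size of the change depends on the bottom of the array's range, and it was 6.09 without MK-8776 replicate 1 and 7.59 without MK-8776 replicate 2. THBS1, which encodes the matrix protein thrombospondin 1 (chromosome 15, 39581079 to 39599466), rose by 6.59 (SE 0.44, adjusted p = 0.000649, limma), from 5.74 ± 0.96 to 12.33 ± 0.59. The complement receptor gene C5AR1 rose by 4.46, the formyl peptide receptor gene FPR2 by 3.89 and the chemokine gene CCL2 by 4.22. S100A8 and S100A9, which encode the subunits of calprotectin, rose by 4.28 and 4.22. NQO1, an antioxidant enzyme gene, rose by 4.18, and PLIN2, which encodes a coat protein of lipid droplets, rose by 3.97. VNN2, AQP9, which encodes a water and glycerol channel, and GPR183 rose by 4.32, 3.93 and 3.44. The adjusted p of these 12 genes ran from 0.000170 for C5AR1, VNN2 and S100A8 to 0.00458 for S100A9 in the limma fit.

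The largest falls were in SLC6A8, the creatine transporter gene (feature TC0X00008794.hg.1, chromosome X, 153687926 to 153696593), from 13.83 ± 0.83 to 9.69 ± 0.18, and in ALDOC, a glycolytic aldolase gene (chromosome 17, 28573120 to 28576895), from 12.63 ± 0.50 to 8.51 ± 0.81. These are changes of -4.14 (SE 0.36, adjusted p = 0.00154) and -4.12 (SE 0.39, adjusted p = 0.00243, limma). SCD, a fatty acid desaturase gene, fell by 2.95. MYC fell by 2.71, the replication licensing gene CDT1 fell by 2.79 and the mitotic kinesin gene KIF20A fell by 2.75. NRN1 and TMEM45A changed by -2.70 and -2.59, the last to a level under the lower quartile of all values. FAM72A, FAM72C and FAM72D changed by -2.68, -2.62 and -2.82, and the metallothionein gene MT1X by -2.63. The FAM72 genes are near-identical copies of one another and MT1X has close paralogs, so how much of each signal comes from the named copy is uncertain.

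**Figure D1:**
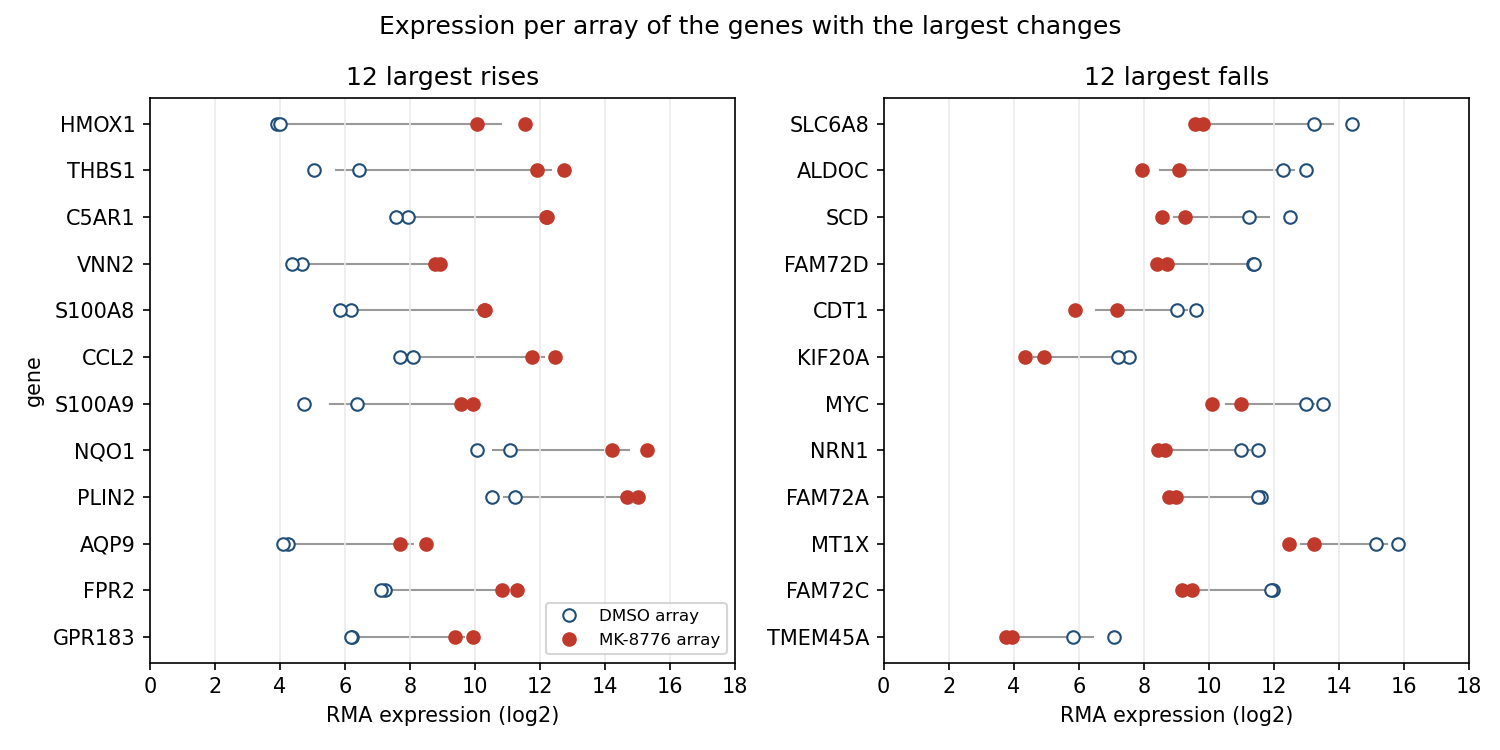
Expression per array (x axis, RMA log2 value) of the 12 genes with the largest rise (left) and the 12 with the largest fall (right) among those past the threshold. Open points are the 2 DMSO arrays, filled points the 2 MK-8776 arrays and grey lines join the group means, with HMOX1 at 3.92 and 4.00 in DMSO against 11.55 and 10.05 in MK-8776, and no overlap between the groups in any of the 24 genes.

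CHEK1, which encodes CHK1 (feature TC1100013111.hg.1, chromosome 11, 125625136 to 125681124), measured 11.02 ± 0.16 in DMSO and 10.21 ± 0.18 in MK-8776, a change of -0.81 (SE 0.22) that missed the threshold (adjusted p = 0.0883, limma) and passed it with a variance trend (0.0333) or among features above the median level (0.0492). Of 18 measured genes of the ATR-CHK1 checkpoint list, 1 rose, 1 fell and 16 did not pass, and adjusted over the list alone 1 rose and 3 fell. CLSPN, which encodes the CHK1 adaptor claspin, rose by 1.04, and CDC25C, a phosphatase gene of mitotic entry, had a change of -0.995, a fall that passed at adjusted p = 0.0372 (limma). The list's median change was -0.39 (camera adjusted p = 0.0257, adjusted p = 0.560 with an estimated correlation). That call was lost without DMSO replicate 1 (0.0595), without DMSO replicate 2 (0.0510), without MK-8776 replicate 1 (0.412) and among features above the median level (0.0900), and the median itself was -0.128 without MK-8776 replicate 1 and -0.248 without DMSO replicate 2.

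Most mitotic genes fell. Of 31 measured, 26 fell, 0 rose and 5 did not pass, and 29 fell when adjusted over the list alone. The kinesin gene KIF20A changed by -2.75, the centrosome kinase gene NEK2 by -2.03, the cyclin B gene CCNB2 by -2.00 and the spindle gene DLGAP5 by -2.00. The median change was -1.54 (camera adjusted p = 2.81e-29, adjusted p = 0.399 with an estimated correlation). Of 39 measured DNA replication genes, CDT1 alone fell, 0 rose and 38 did not pass, with 10 falls adjusted over the list alone, and the median change was -0.50 (camera adjusted p = 4.45e-07, adjusted p = 0.560 with an estimated correlation). Of 21 genes of homologous recombination and Fanconi repair, 2 fell and 19 did not pass, with 4 falls adjusted over the list alone. These were the helicase gene BLM, with a change of -1.42 (adjusted p = 0.0378), and the nuclease gene MRE11, with -0.95 (adjusted p = 0.0433, and 0.0525 with all features tested). This list had a median of -0.54 (camera adjusted p = 0.000322, adjusted p = 0.560 with an estimated correlation). Of 24 replication-dependent histone genes, 0 passed in the limma fit or adjusted over the list alone (3 at an unadjusted p under 0.05), and the list did not shift (camera adjusted p = 0.576). The members with the largest change were H3C2 at -0.90 (under the threshold with a variance trend, 0.0290, or above the median level, 0.0406) and H1-5 at -0.71, and histone genes have near-identical copies.

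Targets of p53, the DNA damage transcription factor, showed no shared direction. Of 23 measured, CDKN1A, which encodes the cell cycle inhibitor p21, rose by 1.79 (adjusted p = 0.0164), AEN fell by 1.19 (adjusted p = 0.0398, limma) and 21 did not pass, with 1 rise and 2 falls adjusted over the list alone. The median was 0.04 (camera adjusted p = 0.762). Pro-apoptotic genes gave 0 calls of 13 in the limma fit, also adjusted over the list alone (2 at an unadjusted p under 0.05), with PMAIP1 at 0.69 and BAD at 0.65, and a median of 0.17 (camera adjusted p = 0.130). Of 8 anti-apoptotic genes, BCL2 fell by 1.71 (adjusted p = 0.00724), CFLAR, which encodes a caspase-8 inhibitor, rose by 1.27 (adjusted p = 0.0406, and 0.0503 with all features tested) and 6 did not pass, with 3 rises and 1 fall adjusted over the list alone (camera adjusted p = 0.325).

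Of 30 measured genes of the neutrophil maturation list, 8 rose, 0 fell and 22 did not pass, with 9 rises and 2 falls adjusted over the list alone. The rises were led by S100A8, S100A9, FPR2 and MMP9, the gelatinase gene, which rose by 2.83 (adjusted p = 0.00221, limma). Whatever the p, 22 of the 30 were higher and 8 lower. LTF, FCGR2A and ITGAM, at -0.95, -0.725 and -0.69, were among the 8 and did not pass. Several members lay under the lower quartile of all values (3.97) in both groups, such as CAMP (3.76 in DMSO, 3.43 in MK-8776), LCN2 (3.535 and 3.70) and MMP8 (3.275 and 3.70). Others that did not pass, such as CSF3R (9.32 and 9.35), were not dim. For the dim members the lack of a call says little, so the list's rise rests on part of its members. The list's median change was 0.24 (camera adjusted p = 0.000103, adjusted p = 0.399 with an estimated correlation). Of 11 measured genes of primary granules and promyelocytes, 3 fell, 0 rose and 8 did not pass, with 7 falls adjusted over the list alone. The granule protease genes CTSG, PRTN3 and PRSS57 changed by -2.20, -2.01 and -1.39, and the list's median was -1.11 (camera adjusted p = 6.20e-06, adjusted p = 0.540 with an estimated correlation). Of 20 monocyte and macrophage genes, 3 rose and 1 fell, with 3 rises and 2 falls adjusted over the list alone. CD86, a costimulatory ligand gene, rose by 1.78, the complement gene C1QA by 1.78 and CD14 by 1.37 (adjusted p = 0.0491, and 0.0572 after quantile normalization and 0.0599 with all features tested), whereas FCGR1A, the high-affinity IgG receptor gene, fell by 2.56 (adjusted p = 0.00855, limma). The list did not shift as a whole (median 0.11, camera adjusted p = 0.382).

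Of 15 measured genes of the retinoic acid response list, 0 passed in the limma fit or adjusted over the list alone, and 1 had an unadjusted p under 0.05. The largest changes were 0.77 for ID2 and -0.47 for CRABP2 (adjusted p = 0.126 and 0.371, limma), with a median of 0.10 (camera adjusted p = 0.576). Some members lay under the lower quartile of all values (3.97) in both groups, such as RARB (2.65 in DMSO, 2.71 in MK-8776) and CYP26A1 (3.685 and 3.855). Others, such as CD38 (11.685 and 11.785), did not. For the dim members the lack of a call says little about a response. Of 18 myeloid transcription factor genes, EGR1 rose by 1.61 (adjusted p = 0.0117), MYC fell by 2.71 (adjusted p = 0.00686, limma) and 16 did not pass, with the same counts adjusted over the list alone, 1 rise and 1 fall (median -0.01, camera adjusted p = 0.762). MHC class II genes gave 0 calls of 9 in the limma fit (1 at an unadjusted p under 0.05) and 1 fall adjusted over the list alone. CD74 was at -1.16 (adjusted p = 0.0545, limma, and under the threshold with a variance trend, 0.0458, or above the median level, 0.0343). CIITA was at -0.38, and the list did not shift (camera adjusted p = 0.325). HLA-DRA (3.05 in DMSO, 2.775 in MK-8776) and HLA-DPA1 (3.555 and 3.41) also lay under that quartile in both groups, unlike HLA-DMA (8.25 and 8.47).

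Of 17 measured NF-kB and inflammation genes, 6 rose, 0 fell and 11 did not pass, with 7 rises adjusted over the list alone. CCL2 rose by 4.22, the cytokine gene IL1B by 2.65, CXCL8, which encodes interleukin 8, by 2.34 and the chemokine gene CCL3 by 1.88. The median was 0.54 (camera adjusted p = 4.45e-07, adjusted p = 0.443 with an estimated correlation). Of 25 type I interferon response genes, 4 fell, 0 rose and 21 did not pass, with 4 falls adjusted over the list alone as well. IFIT1, USP18, BST2 and OASL changed by -2.23, -1.90, -1.32 and -1.04. OASL (adjusted p = 0.0493, limma) missed the threshold after median centring (0.0518) and with all features tested (0.0599), and its MK-8776 level lay under the lower quartile. The list's median was 0.08 while camera's direction was down, and the shift did not pass (camera adjusted p = 0.382).

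Of 18 measured lysosome and autophagy genes, 9 rose, 0 fell and 9 did not pass, with 11 rises adjusted over the list alone. MCOLN1, the gene of a lysosomal calcium channel, rose by 2.42, the autophagy receptor gene SQSTM1 by 2.38, the proton pump gene ATP6V0D1 by 1.90 and the membrane glycoprotein gene LAMP1 by 1.68, with a median of 1.07 (camera adjusted p = 2.78e-10, adjusted p = 0.399 with an estimated correlation). Of 10 heat shock genes, 4 rose, 0 fell and 6 did not pass, with 5 rises adjusted over the list alone. HSPH1, DNAJB1, HSP90AA1 and HSPA1A rose by 2.41, 1.22, 1.05 and 1.02, and HSPA1A has a near-identical neighbour. The list's median was 0.66 (camera adjusted p = 0.00248, adjusted p = 0.401 with an estimated correlation, and 0.0586 at the preset correlation without DMSO replicate 1).

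Of 17 hypoxia and glycolysis genes, 6 fell, 0 rose and 11 did not pass, with 11 falls and 1 rise adjusted over the list alone. ALDOC changed by -4.12, P4HA1, a collagen prolyl hydroxylase gene, by -2.08, the mitophagy gene BNIP3 by -1.98 and NDRG1 by -1.75, with a median of -0.70 (camera adjusted p = 1.95e-06, adjusted p = 0.547 with an estimated correlation). Of 13 genes of the nucleolus and ribosome biogenesis, NOP16 and FBL fell, with changes of -1.12 and -1.10 (adjusted p = 0.0488 and 0.0386, limma, the first 0.0530 after quantile normalization and 0.0594 with all features tested), and 11 did not pass, with 5 falls adjusted over the list alone. The list's median was -0.54 (camera adjusted p = 0.000172, adjusted p = 0.399 with an estimated correlation). The ATF4 integrated stress response list had 1 rise and 1 fall of 22, the cystine transporter gene SLC7A11 at 3.11 (adjusted p = 0.00785) and the serine synthesis gene PHGDH at -1.17 (adjusted p = 0.0382, limma), with 3 rises and 2 falls adjusted over the list alone (camera adjusted p = 0.595). Genes of the ER unfolded protein response gave 0 calls of 15 in the limma fit, also adjusted over the list alone (4 at an unadjusted p under 0.05), with PDIA6 at -0.76 (adjusted p = 0.0850, and 0.00679 with a variance trend or 0.0450 above the median level) and DNAJC3 at 0.74. This list's median was -0.09 while camera's direction was up (camera adjusted p = 0.814). Of 15 cholesterol synthesis genes DHCR7 alone passed, with a fall of 1.68 (adjusted p = 0.0247, limma), and 5 fell adjusted over the list alone (camera adjusted p = 0.189).

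Markers of other blood cell types did not shift as lists. Of 13 lymphoid markers, NKG7 rose by 1.23 and CD3E fell by 1.38, also adjusted over the list alone (camera adjusted p = 0.576). Of 11 erythroid and megakaryocyte markers, PPBP rose by 1.82 and ITGA2B fell by 1.55, with 2 rises and 1 fall adjusted over the list alone (camera adjusted p = 0.697). Of 9 eosinophil, basophil and mast cell markers 0 passed in the limma fit, also adjusted over the list alone (2 at an unadjusted p under 0.05), with EPX at -0.995 and TPSAB1 at 0.86 (median 0.03 against a camera direction of down, camera adjusted p = 0.993). Of 10 housekeeping genes 0 passed in the limma fit (3 at an unadjusted p under 0.05), and 1 rise and 2 falls passed adjusted over the list alone. The largest changes were -0.84 for PGK1, which is also a glycolytic gene and passed with a variance trend (0.0134), and -0.74 for HPRT1 (median 0.03 against a camera direction of down, camera adjusted p = 0.860).

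Of the 27 lists, 11 shifted by camera at the preset correlation, 4 upward and 7 downward. With the correlation estimated from these 4 arrays 0 lists passed (smallest adjusted p = 0.399, and 1 list at an unadjusted p under 0.05), and fry passed 0 (smallest adjusted p = 0.0819, and 10 lists at an unadjusted p under 0.05). Camera with an estimated correlation has 2 degrees of freedom, so few lists could pass it. For heat shock the estimate was -0.019, under the preset 0.01, yet the unadjusted camera p went from 0.000918 to 0.0743. The lack of calls thus cannot tell whether correlation between genes made the shifts.

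**Figure D2:**
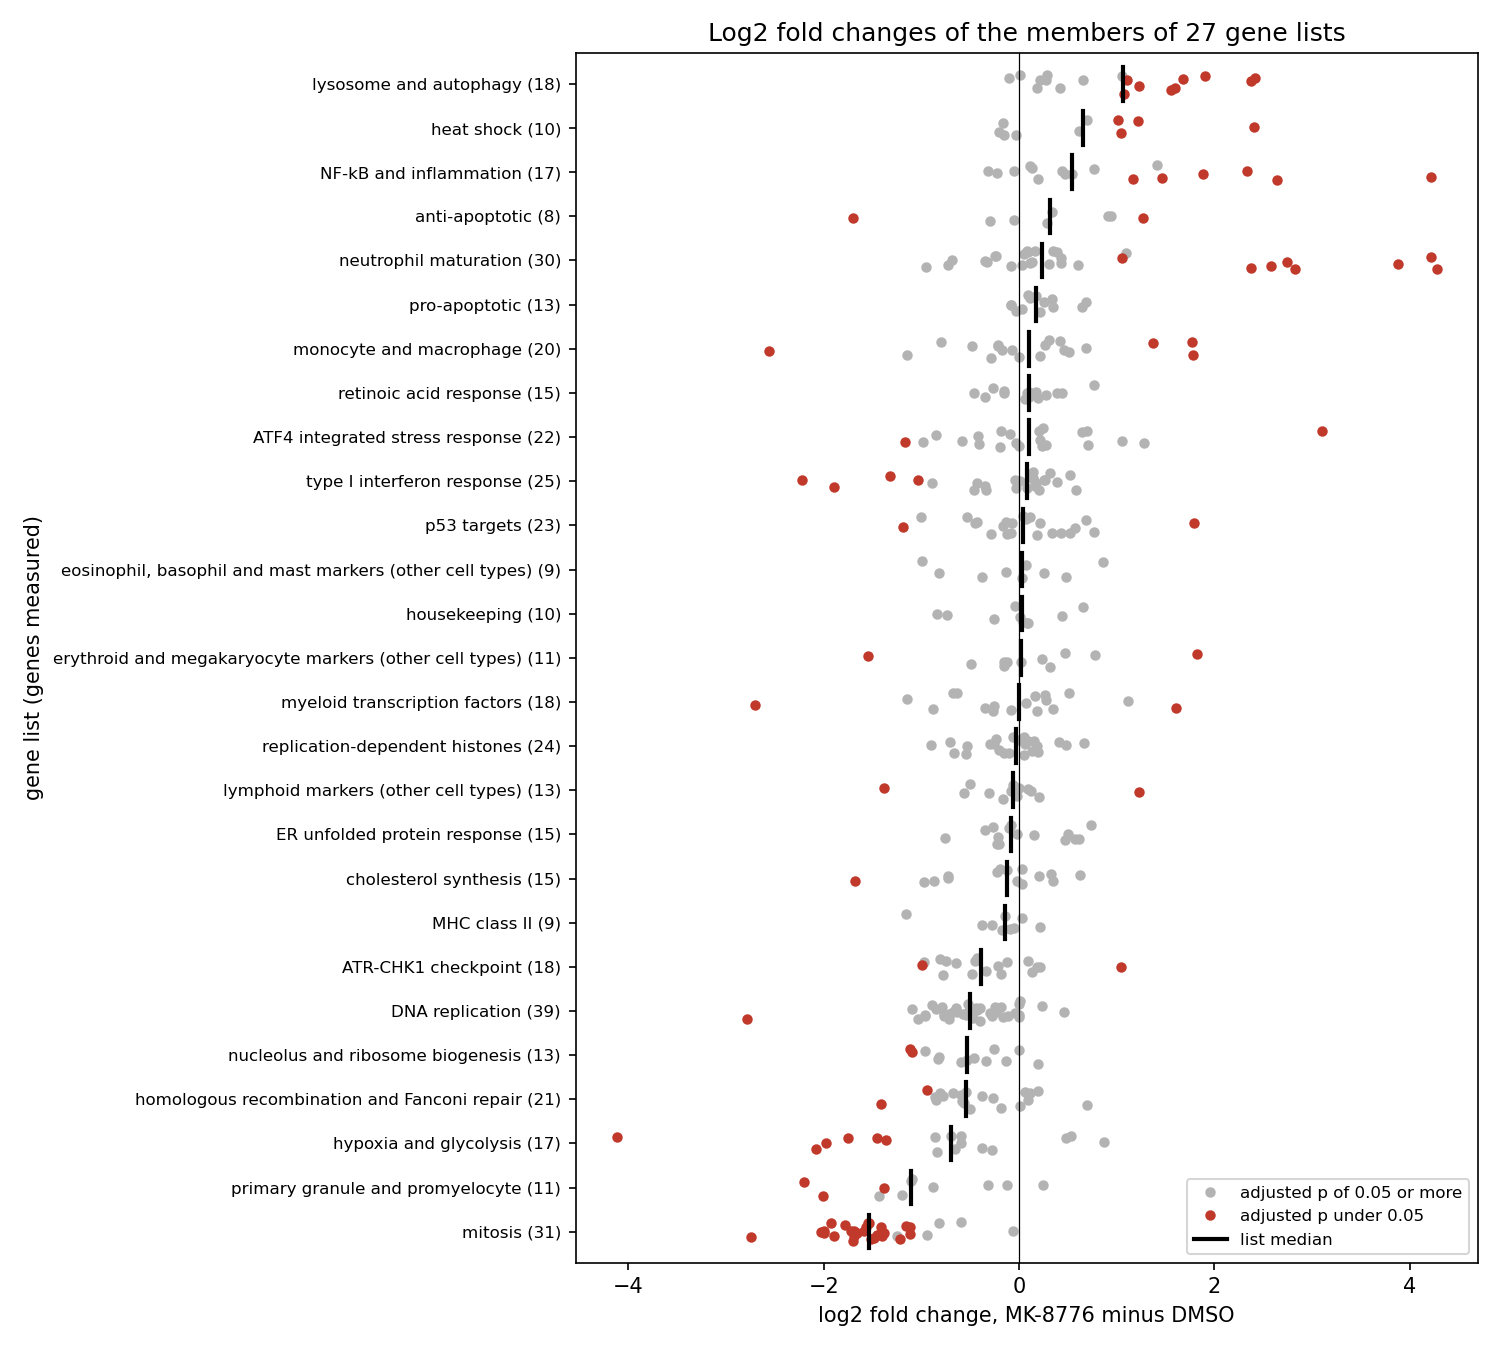
Log2 fold changes (x axis, MK-8776 minus DMSO) of the measured members of the 27 gene lists (y axis, number of genes measured in parentheses), with red points at an adjusted p under 0.05, grey points for the other genes and a black bar at the list's median. The medians run from 1.07 for lysosome and autophagy genes to -1.54 for mitotic genes.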

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

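Of the 3739 array features with no gene symbol here, which no comparison above uses, 67 passed the threshold when all 21448 features were tested together with limma. Of the 21448, 629 passed, so the unnamed features passed less often than features at large. Of the 67, 35 were higher in MK-8776 than in the DMSO arrays and 32 lower. The 35 drew attention only as a signal in data left out of the comparisons. No explanation was tested for them.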

How the results depend on the processing

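The count of 652 genes stayed within 1.5 times after quantile normalization, median centring, among features above the median level and with all features tested, where it ran from 620 to 943. The 943, among features above the median level, came from 9184 genes tested, a larger share than 652 of 17687. The count was 1185 with a variance trend, 1162 with trend and robust estimation and 288 when tested against a fold of 1.2. The 610 genes of 2-fold or more became 652 with a fold of 1.5 in place of 2. The replicate block gave 309 genes, all 2-fold or more (309 against 610), of which 294 were among the 652. It changed no list call, and 20 of the 71 named genes past the threshold missed it under the block. The replicate numbers are not known to pair the samples. The differences of replicate 1 from replicate 2 in the groups correlated at 0.139 across genes. Some lists moved alike from replicate 1 to replicate 2 in both groups. The histone mean went from 9.802 to 10.185 in DMSO and from 9.714 to 10.092 in MK-8776. Others did not, such as the mitotic mean, from 9.896 to 9.827 in DMSO and from 8.191 to 8.565 in MK-8776. A shared replicate effect is thus not ruled out, and whether 309 or 652 is the fitter count cannot be told. With 3 arrays the counts ran from 0 to 34, for 2-fold genes from 0 to 34 as well. Such fits leave 1 residual degree of freedom and assume that the lone array varies like the other group. In simulated data 3 arrays recovered 82.6% of genes changed by 2 on the log2 scale, against 96.2% with 4. For genes changed by 1 the simulated recovery was 4.1% with 3 arrays, against 13.5% with 4. The simulated false share of calls was 11.2% with 3 arrays, against 5.95% with 4. The loss of nearly all calls here is larger than these simulated losses, and its cause was not tested. The share of rises among the calls stayed between 42.8% and 47.7% in the fits with 4 arrays, and the median change of all genes was 0.004 to 0.015 under the scalings. The count of 11 shifted lists was 0 with an estimated correlation and 0 by fry, and 9 to 11 without each array. The median SD per gene of 0.208, pooled over both groups, was 0.199 among features above the median level. With 1 array left out it was 0.163 to 0.170, which are the median SDs within the group that kept 2 arrays. That drop is thus no sign of a smaller spread. Of the 71 named genes past the threshold, 66 passed in every fit with another scaling, filter, variance model or set of features that tested them. The 2 lists whose call was lost with an array left out or among the brighter features were the ATR-CHK1 checkpoint and heat shock.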

Other observations

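The gene families and tests in this part were chosen after the changes had been seen, and only the mitotic, DNA replication and housekeeping lists were fixed before. Apart from the NRF2 targets no family was tested as a set. Of 28 measured targets of NRF2, the transcription factor of the antioxidant response, 11 rose and 0 fell in the limma fit, with 13 rises and 2 falls adjusted over the list alone, and SLC7A11 also stands in the ATF4 list. HMOX1 rose by 6.84, NQO1 by 4.18, SLC7A11 by 3.11, the glutathione synthesis gene GCLM by 2.89, the malic enzyme gene ME1 by 2.33 and the thioredoxin reductase gene TXNRD1 by 1.55, whereas BLVRB, at -0.89, did not pass (adjusted p = 0.175, limma). Of 12 lipid genes, 3 rose and 6 fell, with 3 rises and 8 falls adjusted over the list alone and a median change of -1.175. PLIN2, the acyltransferase gene GPAT3 and the fatty acid uptake gene CD36 rose by 3.97, 3.33 and 2.07, while SCD, the lipid synthesis regulator gene SREBF1, TMEM97, DHCR7, the desaturase gene FADS2 and the cholesterol exporter gene ABCA1 changed by -2.95, -1.96, -1.83, -1.68, -1.37 and -1.37. DHCR7 also stands in the cholesterol synthesis list.

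Of 11 genes of complement and chemoattractant sensing, 7 rose and 0 fell, with 8 rises adjusted over the list alone, among them C5AR1 by 4.46, FPR1 by 2.58, C3 by 2.50 and CR1 by 1.83. Of the 7, FPR1, FPR2 and C1QA also stand in the fixed neutrophil or monocyte lists. Of 7 Fc receptor genes, 1 rose and 3 fell, with 1 rise and 4 falls adjusted over the list alone. FCGR1A (also in the fixed monocyte list), FCGR2B and FCGR2C changed by -2.56, -2.17 and -1.56, and FCER1G, which encodes the signalling chain that the FCGR1A receptor uses, rose by 1.32. FCGR2B and FCGR2C are close paralogs. Of 15 subunits of the V-ATPase, the lysosomal proton pump, 4 rose, 0 fell and 11 did not pass, with 6 rises adjusted over the list alone and 13 higher whatever the p. Of the 4, ATP6V0D1 and ATP6V1H also stand in the lysosome list. Of 28 proteasome subunits 3 rose, 0 fell and 25 did not pass, with 7 rises adjusted over the list alone, 25 higher whatever the p and a median change of 0.51.

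HMOX1, NQO1, SLC7A11 and GCLM rose together. A shift between arrays left by the normalization would move genes at large by about the same amount. The housekeeping list had a median change of 0.028 (SD over genes 0.462). Genes within 0.5 of the DMSO level of each of the 4 had medians from -0.07 to 0.025 (SD over genes up to 0.598). No such shift of genes at large was thus left in the deposited values. RMA makes the arrays alike in distribution, so these medians were largely set near 0 in advance and are no independent test of this source. A single aberrant array is argued against as the source of the rise. The smallest change of the 4 genes without each array in turn was 2.365, against SDs within a group of up to 1.06, and both MK-8776 arrays exceeded both DMSO arrays by at least 2.18 in each gene. The genes were chosen for large changes in separated groups, so this leaves no room for one array as the whole source but is no independent test of the rise. A wider rise of NRF2 targets stays open. The other 24 measured targets had a median change of 0.42, and 7 of them passed, all upward. Camera gave an unadjusted p of 1.91e-05 for these 24 at the preset correlation and 0.190 with the estimated correlation of 0.213, for a list put together after the changes were seen. The 0.190 also comes from a test with 2 degrees of freedom and little power.

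Mitotic genes fell further than DNA replication genes, with medians that differed by -1.04. The mean of the mitotic genes minus that of the replication genes was 0.50 and 0.19 in the DMSO arrays and -0.62 and -0.63 in the MK-8776 arrays. Compression of changes at low signal is argued against by the levels. The mean DMSO level was 9.86 for the mitotic and 9.52 for the replication genes, both above the median of all values (5.77). At equal DMSO level the difference was -0.96 (95% interval over genes -1.20 to -0.72, genes not being independent replicates). With levels so close this adjustment could move the difference little, so it adds little. A single aberrant array is argued against too, as the difference stayed between -1.16 and -0.87 without each array in turn. A change in the share of cells in each phase of the cycle after MK-8776 stays open and was not tested.

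Metallothionein genes and the FAM72 copies fell together, with 12 of 15 measured members past the threshold, 8 of 11 metallothioneins and 4 of 4 FAM72 copies. The FAM72 genes changed by -2.59 to -2.82, and MT2A and MT1G by -2.39 and -2.42. Whether these are changes of several genes or one signal shared between near-identical copies cannot be told apart, because probe sequences were not used here. The metallothionein genes MT1F (-0.46), MT4 (-0.415) and MT3 (0.53) did not pass, with adjusted p of 0.492, 0.393 and 0.359 (limma).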
